A study of Mus musculus with 12 samples.

How the data were processed

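RNA from sorted podocytes of 6 control and 6 Npr1_KO mice was compared. Per the labels' protocols, glomeruli were isolated with magnetic beads, digested with enzymes and sorted by fluorescence, total RNA was purified with a column kit, and libraries were made with a stranded kit for polyadenylated mRNA. The labels state that each group came from 6 separate mice.

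The authors deposited a table of raw read counts per gene and a table of TPM values for the same 12 libraries and 31889 genes. Per the submitters' processing notes, STAR, Picard and featureCounts 1.6.3 were used with the build GRCm38. The settings, the annotation and the strand setting are not given in the sources used here. The deposited TPM sum to 1e+06 in every library, and for 95.6% of 19115 genes the length they imply from the counts lies within 1% of the exon length in GENCODE mouse release 21. That annotation (GRCm38) supplied gene symbols and positions for 31832 genes, and 57 had no match. The columns of both tables name the group and a running number, but not the replicate number of the labels, so columns were assigned to groups only. No library was a copy of another.

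The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the deposited counts, with filterByExpr, TMM scaling, robust dispersion and genotype as the only term, leaving 10 residual degrees of freedom. Of 19129 genes with at least 1 count, 12469 were tested. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The standard error of a log2 fold change was derived from the test statistic. Gene lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists tested of 32 fixed. Camera with an estimated correlation and fry were alternatives. Levels of libraries and of list means were compared with two-sided exact permutation tests over 924 assignments. List means used log2 CPM with a prior count of 2. Called genes were also counted with the adjustment made within each list.

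The gene lists, the main design, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named Npr1 and Pros1, the 15 higher and 15 lower genes with the smallest adjusted p and a mean of at least 2 CPM, and for each list up to 4 changed members with the smallest adjusted p or, where none changed, its 2 most abundant members. Genes outside the rule were chosen after their values were seen. Among them, Itgb1, Msn, Nck2, Ildr2, Bmp4, Bmp7, Igf1, Bst2 and Bcl2 complete the changed members of a list.

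On simulated counts for 12339 genes, with 100 genes planted at each fold size, the procedure recovered 74% of genes changed by 1 on the log2 scale and 40.6% of those changed by 0.5. It made 131 calls, of which 6 (4.58%) were false, none in the wrong direction, and called 0 of 30 unchanged lists. That simulation drew genes independently of each other.

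Alternatives were other scalings (RLE, upper quartile, none), no low-count filter or a mean of at least 5 CPM, non-robust dispersion, DESeq2 1.42.0, limma voom with and without quality weights, an adjusted p of 0.1, a fold of at least 1.5, 1 surrogate variable (sva 3.50.0), covariates for tubule, endothelial and stress transcripts and library size, mitochondrial genes left out, limma trend on log2 TPM with pseudocounts of 1 and 0.1, and each library left out in turn. Leaving out control S5 and Npr1_KO S11 together, covariates for both tubule lists, a mesangial covariate and leaving out chromosome 3 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.

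Total counts were 25194822 to 32813032 per library. In units of 1e+06 counts, the mean was 28.2 ± 2.21 in controls and 30.1 ± 1.78 in knockouts (two-sided exact permutation p = 0.154). The biological coefficient of variation was 0.256, so the spread between mice, not counting error, limited the precision for genes at more than a few CPM. Sequencing batches are not given in the sources used here.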

Results

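Podocytes are the epithelial cells that wrap the glomerular capillaries of the kidney. NPR-A, also called GC-A, is the membrane guanylyl cyclase that binds the cardiac natriuretic peptides and makes cGMP. To ask which podocyte transcripts depend on this receptor in unchallenged animals, RNA was sequenced from podocytes of mice at 8 weeks of age. The cells were sorted by green fluorescence, which a Cre-dependent reporter switches on in podocytes. In 6 mice (Npr1_KO) a Cre recombinase driven by the podocin promoter met floxed alleles of Npr1, the gene for NPR-A, and 6 control mice carried the same Cre with wild-type alleles. Each mouse gave 1 library, named S1 to S6 for the controls and S7 to S12 for the knockouts. The gene counts of the 12 libraries summed to between 25194822 and 32813032, with 15089 to 16049 genes detected. Levels are CPM, the counts of a gene per 1e+06 counts of its library after TMM scaling, as mean ± SD.

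Npr1 transcripts were nearly lost from the knockout podocytes. The gene (ENSMUSG00000027931, chromosome 3, 90450591 to 90465866, GRCm38) had 777 ± 80.1 CPM in controls and 6.31 ± 2.41 CPM in knockouts (n = 6 each). Raw counts ran from 17421 to 26524 in the control libraries and from 117 to 287 in the knockout libraries, so every library matched its label. The log2 fold change was -6.94 (SE 0.255, adjusted p = 1.80e-08), a 123-fold lower level. An antisense gene annotated inside Npr1, Gm16048 (90451583 to 90457095, opposite strand), went the other way, with 0 to 3 counts in control libraries and 57 to 140 in knockout libraries. Gm16048 was singled out after its values were seen. The strand setting of the counting is not given in the sources used here, so reads of Npr1 and of Gm16048 cannot be fully told apart.

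Pros1, which encodes the anticoagulant protein S, was also lower in the knockouts. Its level (ENSMUSG00000022912, chromosome 16, 62854307 to 62929346) was 336 ± 112 CPM in controls and 63.6 ± 17.0 CPM in knockouts, a 5.28-fold difference with no overlap between the groups. The log2 fold change was -2.40 (SE 0.237, adjusted p = 9.84e-05). Of the 19 tested genes in the list on coagulation, protein S and its receptors, Pros1 and Thbd fell and F2r rose, both over all genes and adjusted over the list alone. Thbd, the gene of thrombomodulin, went from 4.55 ± 2.35 to 1.43 ± 0.435 CPM (log2 fold change -1.67, adjusted p = 0.0114). F2r, the gene of the thrombin receptor PAR1, went from 134 ± 18.7 to 328 ± 99.0 CPM (1.29, adjusted p = 0.00155). As a set the list did not pass the test (camera adjusted p = 0.799, and 0.962 with an estimated correlation). Thbd lost its call in 2 of 34 alternatives, limma voom with quality weights and unfiltered TPM.

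**Figure D1:**
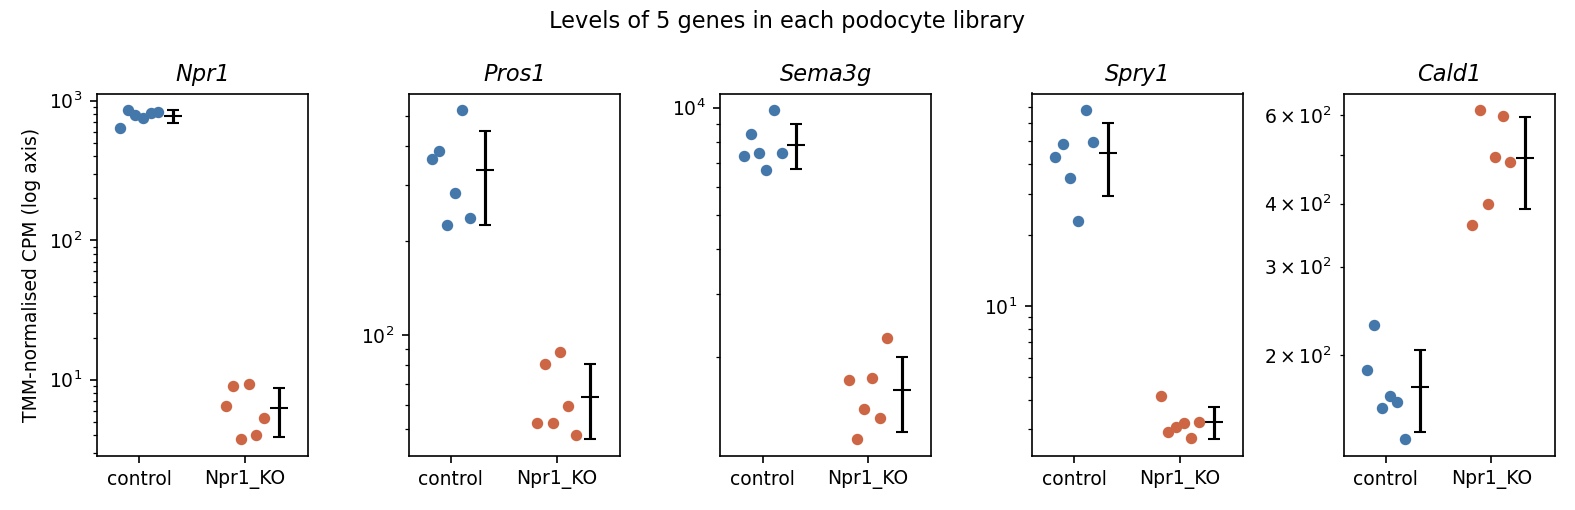
TMM-normalised CPM on a log axis for Npr1, Pros1, Sema3g, Spry1 and Cald1, with 1 point per library (6 control, 6 Npr1_KO) and the group mean with its SD as the bar beside the points. The groups do not overlap for any of the 5 genes, and Pros1 falls from a mean of 336 to 63.6 CPM.

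Among 12469 genes tested with edgeR, 347 were higher and 344 lower in knockouts, 691 in all. The median fold of the changed genes was 1.53, and 102 genes in each direction changed at least 2-fold. In 429 of the 691 the groups did not overlap. Of all genes tested, 495 had no overlap, where chance would give 27 (0.216%). DESeq2 called 1115 genes. Without control S5 and Npr1_KO S11, the libraries of each group with the most tubule transcripts, 447 genes passed, and without Npr1_KO S9 the number of lower genes was 228.

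The genes that fell most reliably included several signalling regulators and a secreted product that podocytes make in large amounts. Sema3g, a secreted semaphorin, dropped from 7867 ± 1122 to 1612 ± 386 CPM (log2 fold change -2.29, SE 0.155, adjusted p = 1.86e-06). Spry1, an inhibitor of receptor tyrosine kinase signalling, dropped from 44.5 ± 15.2 to 3.21 ± 0.495 CPM (-3.79, SE 0.234), and Dusp6, the phosphatase of ERK, from 323 ± 28.5 to 168 ± 13.1 CPM (-0.94, SE 0.073). The cyclic nucleotide phosphodiesterase genes Pde7b and Pde10a had log2 fold changes of -3.65 and -4.82, from 20.97 and 14.4 CPM to 1.67 and 0.504 CPM. Adgrg6, an adhesion G protein-coupled receptor, fell by 4.32 on the log2 scale, Tspan11 by 2.90 and Top1mt, the mitochondrial topoisomerase, by 2.43. The sizes for Adgrg6, Pde10a, Pde7b and Tspan11 depended on the scale, since on log2 TPM with a pseudocount of 1 they were -1.89, -2.01, -2.20 and -1.94. Lpin2, a phosphatidate phosphatase, fell from 436 ± 17.0 to 154 ± 31.6 CPM, and Ntrk3, the receptor of neurotrophin-3, from 180 ± 20.9 to 76.0 ± 9.39 CPM. Arl5a, S100a11 and Dcdc2a had log2 fold changes of -1.02, -0.97 and -0.86. Rps3a1, a ribosomal protein gene, fell from 407 ± 45.7 to 111 ± 16.2 CPM. Reads of ribosomal protein genes can be shared with processed copies, which was not tested for this gene. The adjusted p of the 15 lower genes chosen by rank, Npr1 among them, was at most 1.58e-05.

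Among the 15 higher genes chosen by rank, Cald1, the actin-binding caldesmon, went from 173 ± 32.1 to 492 ± 101 CPM (log2 fold change 1.51, SE 0.15, adjusted p = 6.71e-05), and Dock8, a guanine nucleotide exchange factor, from 198 ± 37.1 to 482 ± 73.3 CPM (1.29, SE 0.133). Car14, a membrane carbonic anhydrase, rose from 11.6 ± 3.25 to 45.0 ± 6.82 CPM (1.96), and the transcript 2610204G07Rik from 3.97 to 23.5 CPM (2.57). Pkig, an inhibitor of protein kinase A, rose from 103 ± 5.68 to 159 ± 10.4 CPM, Spint2, a serine protease inhibitor, from 125 ± 8.40 to 197 ± 14.0 CPM, and Ager, the receptor for advanced glycation end products, from 18.6 ± 1.87 to 31.7 ± 1.74 CPM. Btd, Asb13, Snapin, Mcm6 and Ilf2 had log2 fold changes between 0.51 and 0.88. Gm16316, BC028528 and 6330410L21Rik rose by 1.56, 1.74 and 1.24 on the log2 scale. Gm16316 is annotated as antisense inside Pkig, and 6330410L21Rik as antisense overlapping Egf, which was also higher. As the strand setting is not given, reads of these overlapping genes cannot be fully told apart. The adjusted p of these 15 genes was at most 0.000105. The groups did not overlap for any of the 30 genes chosen by rank. Of the 30, 9 lie on chromosome 3, as Npr1 does. These are Snapin, Ilf2, Car14, BC028528 and 6330410L21Rik among the higher ones and Npr1, Rps3a1, Spry1 and S100a11 among the lower ones.

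Changed genes were more frequent on chromosome 3 than elsewhere. Leaving out Npr1, 64 of 594 tested genes on chromosome 3 changed (10.77%, 28 higher and 36 lower), against 625 of 11868 on other chromosomes (5.27%, two-sided Fisher's exact test over genes, p = 2.66e-07, with genes not independent of each other). Within 2 Mb of Npr1 the share was 13.24% (9 of 68), and between 2 and 10 Mb it was 18.38% (25 of 136). Gm16048, annotated inside Npr1, was kept and is among these 64 and 9 changed genes. From 10 to 50 Mb away it was 8.49% (22 of 259), and further out 6.11% (8 of 131). Slc27a3, a fatty acid transport protein gene near Npr1 (90385239 to 90389938), rose from 116 ± 36.3 to 312 ± 44.2 CPM. It was picked after its value was seen.

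**Figure D2:**
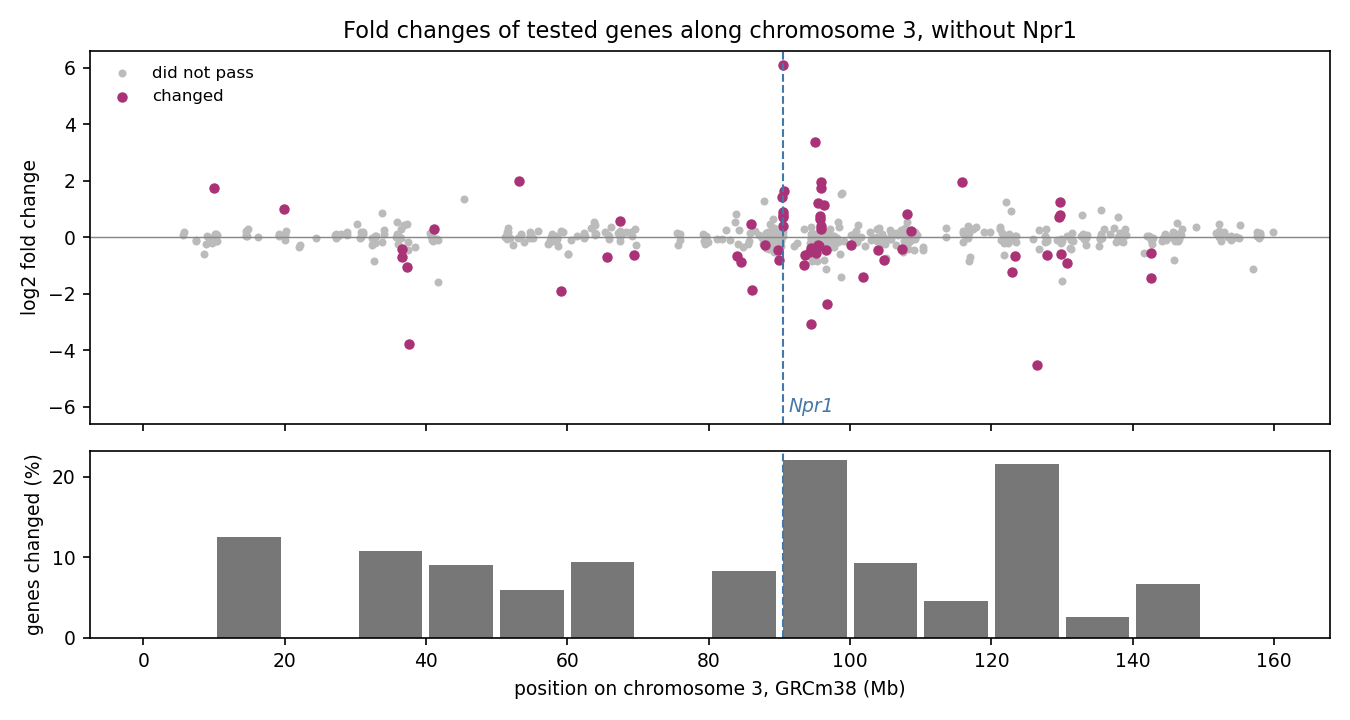
Log2 fold change (upper panel) of the 594 tested genes on chromosome 3 other than Npr1 by position in Mb on GRCm38, changed genes in purple, and the percentage of tested genes that changed in each window of 10 Mb (lower panel, 10 to 118 genes per window), with the position of Npr1 as a dashed line. The window from 90 to 100 Mb holds 26 changed genes of 118 (22.0%), Gm16048 inside Npr1 among them, and that from 120 to 130 Mb holds 8 of 37 (21.6%).

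Members of the cGMP and natriuretic peptide list that changed were all lower. Of 19 tested, Npr1, Pde10a and Npr2 fell and none rose. Adjusted over the list alone, 4 fell and 2 rose. Npr2, the gene of the receptor for C-type natriuretic peptide, went from 8.93 ± 2.91 to 3.71 ± 1.15 CPM (log2 fold change -1.27, adjusted p = 0.00983). Npr3, the clearance receptor, was at 729.8 ± 86.8 and 767 ± 68.0 CPM, and Prkg1, a cGMP-dependent kinase, at 47.7 ± 6.73 and 54.4 ± 7.49 CPM, neither past the threshold. Both of these were picked after their values were seen. The list was lower by camera (adjusted p = 8.97e-05, 0.0541 with an estimated correlation), but its median log2 fold change was 0.07 while its mean was -0.63. The call was lost in 7 of 37 alternatives, voom and TPM fits and leaving out chromosome 3 with Npr1 among them (adjusted p up to 0.612).

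Most podocyte identity genes did not pass the test. Of 47 tested slit diaphragm and identity genes, 4 fell and 3 rose (6 and 9 adjusted over the list alone), and the list did not pass as a set (camera adjusted p = 0.570, 0.962 with an estimated correlation). Over all genes tested, 691 of 12469 changed. With changes in either direction counted, the list passed by fry (adjusted p = 2.52e-08), as 20 of the 30 lists did. The lower members were Sema3g, Nck2, Rhpn1, a Rho-binding protein gene (1289 ± 287 to 604 ± 116 CPM), and Tdrd5 (442.5 ± 79.7 to 269.6 ± 20.99 CPM). The higher members were Ildr2, Bmp7 and Cdkn1c. Cdkn1c, the gene of the cell cycle inhibitor p57, rose from 3679 ± 464 to 5159 ± 544 CPM (log2 fold change 0.49, adjusted p = 0.0128). Its call was lost in 2 of 35 alternatives, a fold of at least 1.5 and unfiltered TPM. Nphs1, the gene of nephrin, had 4191 ± 445 and 4129 ± 755 CPM. Nphs2, whose promoter drives the Cre in both groups, had 13980 ± 1484 and 11220 ± 1148 CPM (log2 fold change -0.32, adjusted p = 0.0710). As a share of all counts Nphs2 was 1.40% ± 0.148 and 1.12% ± 0.0771 (two-sided exact permutation p = 0.00217, the smallest that 924 assignments can give, 1 of 8 library measures tested). Nphs1 and Nphs2 were added after their values were seen.

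Cytoskeletal genes that changed all rose. Of 50 tested actin and focal adhesion genes, 7 were higher and 0 lower (7 and 1 adjusted over the list alone), and these were Cald1, Acta2, Cnn2, Myl12a, Itgb1, Tagln and Msn. Acta2, the smooth muscle actin, was rare in both groups (1.70 ± 0.383 and 5.04 ± 1.01 CPM). Cnn2, a calponin, went from 86.6 ± 13.4 to 150.5 ± 17.7 CPM, and Myl12a, a regulatory myosin light chain, from 704 ± 50.3 to 907 ± 94.0 CPM. The list was higher by camera (adjusted p = 0.00490), not with an estimated correlation (adjusted p = 0.930), by fry (0.318), with limma voom and quality weights (0.0538), with library size as covariate (0.102) or without Npr1_KO S8 (0.136). With library size as covariate 4 of the 7 genes passed, without Itgb1, Tagln and Msn. Acta2 and Tagln are also markers of mesangial, smooth muscle and juxtaglomerular cells. Of 15 such markers tested, these 2 alone rose and none fell (4 and 0 adjusted over the list alone), with a median log2 fold change of 0.62 (camera adjusted p = 0.00202, 0.248 with an estimated correlation). Tagln, the gene of transgelin, had 58.0 ± 22.4 and 131 ± 39.2 CPM. Its call ended in 8 of the 12 fits that left out 1 library, with an adjusted p of up to 0.0714.

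Matrix genes with a change were likewise higher. Of 34 tested, Bgn, Col4a1 and Nid1 rose and none fell (8 and 0 adjusted over the list alone), at low levels. Bgn, a small proteoglycan gene, went from 8.36 ± 2.15 to 18.3 ± 5.10 CPM (log2 fold change 1.13, adjusted p = 0.00598), Col4a1 from 4.14 ± 1.57 to 8.78 ± 2.72 CPM and Nid1 from 1.90 ± 0.432 to 3.58 ± 1.20 CPM. The list was higher by camera (adjusted p = 0.000289), not with an estimated correlation (0.563) or by fry (0.106). Col4a1 lost its call without control S2, S3 or S6 or Npr1_KO S9 (adjusted p up to 0.0588), and Nid1 in 10 of the 12 fits without 1 library (up to 0.1). Both also lost it with library size as covariate (adjusted p = 0.0757 and 0.127) and with the mesangial covariate (log2 fold changes 0.86 and 0.63, adjusted p = 0.110 and 0.140), so mesangial transcripts were not ruled out as a source of their rise.

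In the TGF-beta, BMP and Smad list, 4 of 34 tested genes rose and 2 fell (6 and 2 adjusted over the list alone). Tgfb2, a TGF-beta ligand, went from 5.74 ± 2.83 to 21.2 ± 7.66 CPM (log2 fold change 1.88, adjusted p = 0.00851), and Ltbp2, a latent TGF-beta binding protein gene, from 0.0498 ± 0.0523 to 1.38 ± 0.820 CPM. Id1 and Id3, classical BMP target genes, fell from 8.22 ± 1.51 to 2.96 ± 0.540 CPM and from 9.38 ± 3.27 to 4.40 ± 0.950 CPM. Tgfb2 and Id3 fell short with library size as covariate (adjusted p = 0.0512 and 0.0526). The ligand genes Bmp4 and Bmp7 were the other higher members. As a set the list did not pass (camera adjusted p = 0.377, 0.930 with an estimated correlation).

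Of 24 tested growth factor genes, 3 rose and 2 fell (6 and 2 adjusted over the list alone). Egf, which lies on chromosome 3, rose from 694 ± 26.6 to 1184 ± 162 CPM (log2 fold change 0.77, adjusted p = 0.000154) and Edn1, the gene of endothelin-1, from 2.40 ± 0.739 to 6.40 ± 2.31 CPM. Igf1 (0.174 to 0.666 CPM) was the other higher gene, and Sema3g and Tgfa (85.3 ± 9.94 to 65.3 ± 3.81 CPM) were lower. The camera adjusted p was 0.570 (0.930 with an estimated correlation). In the calcium and calcineurin list, Rcan2, a calcineurin regulator, rose from 15.8 ± 6.27 to 50.7 ± 13.1 CPM and P2rx4, an ATP-gated channel gene, from 117 ± 9.69 to 154 ± 13.7 CPM. These were 2 of 24, with none lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.261). None of 21 renin-angiotensin and corticosteroid genes changed, over all genes or adjusted over the list alone (camera adjusted p = 0.918). Its most abundant members Enpep and Mme had 5540 ± 402 and 681 ± 62.6 CPM in controls and 5234 ± 756 and 860.5 ± 141 CPM in knockouts.

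Most interferon-stimulated genes that changed were lower. Of 30 tested, Gbp3, Gbp2, Rtp4 and Bst2 fell and Ifit3 rose (8 and 1 adjusted over the list alone), with a median log2 fold change of -0.34 (camera adjusted p = 0.000337, 0.563 with an estimated correlation). Gbp3, a guanylate-binding protein gene, went from 9.86 ± 4.10 to 3.61 ± 1.07 CPM and Ifit3 from 13.9 ± 3.10 to 28.3 ± 10.1 CPM. Gbp2 (78.9 ± 14.3 to 53.4 ± 9.10 CPM) and Gbp3 lie on chromosome 3. Rtp4 went from 1.41 to 0.648 CPM. The call for Gbp2 was lost in 4, for Rtp4 in 6 and for Ifit3 in 1 of the fits without 1 library (control S6, adjusted p = 0.0512), with an adjusted p of up to 0.0541 for Gbp2 and 0.0629 for Rtp4. Of 15 complement genes, C3 and Serping1, the C1 inhibitor gene, rose, and C1s1 and C1ra, the C1 protease genes, fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.258, fry 0.0211). C3 went from 0.971 ± 0.260 to 2.94 ± 0.656 CPM, Serping1 from 17.0 ± 3.65 to 30.8 ± 7.18, C1s1 from 14.0 ± 7.01 to 5.59 ± 0.976 and C1ra from 13.1 ± 5.50 to 4.92 ± 1.76 CPM. C1s1 lost its call without Npr1_KO S9 (adjusted p = 0.0580) and C1ra without control S6 or Npr1_KO S9 (up to 0.0601), and both lost it with library size as covariate. Serping1 and C1ra fell short with the mesangial covariate and without control S5 and Npr1_KO S11 together (adjusted p under 0.1). No NF-kB target of 20 tested passed over all genes and 3 rose adjusted over the list alone (camera adjusted p = 0.143). Nfkbia had 1451 ± 149.5 and 1762 ± 151 CPM, and Tnfaip3 948 ± 248 and 884 ± 215.5 CPM.

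Few genes of energy metabolism and protein synthesis changed. Of 49 nuclear oxidative phosphorylation genes, Cox6c alone rose (140.2 ± 19.5 to 177 ± 11.8 CPM, adjusted p = 0.0374), and none passed adjusted over the list alone. The list was nonetheless higher by camera (adjusted p = 0.00325), with a median log2 fold change of 0.09. That call was absent with an estimated correlation (adjusted p = 0.930), by fry (0.534) and without control S3, Npr1_KO S7 or Npr1_KO S11 (adjusted p up to 0.125). Cox6c lost its call in 9 of the 12 fits without 1 library (adjusted p up to 0.0821). None of 7 mitochondrially encoded, 25 fatty acid oxidation, 30 unfolded protein response and 52 cytosolic ribosomal protein genes on the lists changed, over all genes or adjusted over the list alone. The camera adjusted p of these lists was 0.632, 0.537, 0.250 and 0.537. The most abundant members, mt-Co1 and mt-Cytb, Ucp2 and Acadm, Hspa5 and Calr, and Rpl4 and Rplp1, had log2 fold changes between -0.25 and 0.23. In 36 cholesterol and lipid genes, Dhcr7, the last enzyme of cholesterol synthesis, fell from 47.8 ± 4.19 to 34.2 ± 4.03 CPM and Elovl6, on chromosome 3, rose from 1.95 ± 0.455 to 3.20 ± 0.446 CPM. Adjusted over the list alone 1 rose and 1 fell, and the camera adjusted p was 0.5625. Elovl6 lost its call in 9 of the 12 fits without 1 library (up to 0.0822).

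Stress and growth control lists held single changes in both directions. Of 42 dissociation stress and immediate early genes, Nr4a3 and Nr4a1 rose and Klf2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.7875). Klf2, a transcription factor gene, went from 193.6 ± 40.2 to 87.8 ± 17.3 CPM, Nr4a3 from 169 ± 41.6 to 361 ± 146 CPM and Nr4a1 from 2214 ± 361 to 3218 ± 550 CPM. Nr4a1 lost its call in 10 and Nr4a3 in 5 of the 12 fits without 1 library (adjusted p up to 0.0846 and 0.0628). Of 33 antioxidant genes, Gstm2, on chromosome 3, and Hmox1, heme oxygenase 1, rose, from 10.8 ± 1.003 to 19.03 ± 3.22 CPM and from 36.1 ± 3.92 to 51.1 ± 7.71 CPM (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.297). Of 30 p53, apoptosis and senescence genes, Plk2 (18.6 ± 2.96 to 47.4 ± 13.2 CPM) and Casp8 rose and Bbc3 (19.9 ± 4.90 to 11.6 ± 2.15 CPM), Mdm2 and Bcl2 fell (3 and 7 adjusted over the list alone, camera adjusted p = 0.258). Casp8 (22.1 to 26.6 CPM) and Mdm2 (58.3 to 47.2 CPM) lost their calls in 10 and 4 of those fits, with an adjusted p of up to 0.0984 and 0.0699. Mcm6, a subunit of the replicative helicase, was the 1 changed gene of 20 in the cell cycle list (10.1 ± 0.643 to 17.6 ± 1.99 CPM, 1 adjusted over the list alone, camera adjusted p = 0.537). Npas2 was the 1 changed gene of 19 clock genes (16.8 ± 2.30 to 10.7 ± 1.66 CPM, 1 adjusted over the list alone, camera adjusted p = 0.250). Of 30 autophagy and lysosome genes, Ctsz and Laptm4a rose and Wipi2 fell, with log2 fold changes of 0.23, 0.26 and -0.18 (2 and 1 adjusted over the list alone, camera adjusted p = 0.5625). These 3 calls ended in 7, 10 and 7 of the 12 fits without 1 library, with an adjusted p of up to 0.0714, 0.0796 and 0.0733.

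Transcripts listed for other kidney cells were present in the sorted podocytes. The mean log2 CPM of 27 proximal tubule genes ran from 2.27 in control S2 to 7.09 in Npr1_KO S11, with no difference detected between genotypes (two-sided exact permutation p = 0.976), and none of the 27 changed (camera adjusted p = 0.929). Kap, an androgen-regulated proximal tubule transcript, had 1253 ± 1004 CPM in controls and 1028 ± 736 CPM in knockouts, and Gpx3 had 883 ± 970 and 873 ± 982 CPM. Of 24 genes of the loop of Henle, distal tubule and collecting duct, Egf rose (1 adjusted over the list alone, camera adjusted p = 0.304). Among controls the mean log2 CPM of this list was lowest in control S2 (0.962) and highest in control S5 (3.53). Egf had 728 and 680 CPM there, so its level did not rise with the list. Of 9 parietal epithelial genes, Aldh1a1 (1.51 ± 0.450 to 4.01 ± 1.67 CPM) and Akap12 (15.3 ± 3.81 to 26.8 ± 6.84 CPM) rose (2 adjusted over the list alone, camera adjusted p = 0.1085). Akap12 lost its call in 8 of the 12 fits without 1 library (adjusted p up to 0.0759). None of 15 endothelial and 6 leukocyte genes changed (camera adjusted p = 0.915 and 0.5625). Tm4sf1 and Lpl had 2034 ± 203 and 1514 ± 152 CPM in controls and 1706 ± 264 and 1407 ± 96.2 CPM in knockouts, and Csf1r and Cd68 had 8.08 ± 1.61 and 0.992 ± 0.360 CPM against 10.2 ± 3.03 and 0.7225 ± 0.311 CPM. The endothelial list mean was lowest in Npr1_KO S8 (0.972 log2 CPM) and highest in Npr1_KO S9 (2.82). In these libraries Tm4sf1 had 2097 and 1497 CPM and Lpl 1538 and 1364 CPM, so neither rose with the list. In control S2 and control S5, with list means of 1.16 and 2.35, Lpl had 1382 and 1777 CPM and Tm4sf1 2139 and 1932 CPM. Which cells the reads of Tm4sf1, Lpl and Egf came from was not tested. Bpgm and Slc4a1 of the erythroid list and Ddx3y and Eif2s3y of the sex-linked list had adjusted p values of 0.634 or more.

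**Figure D3:**
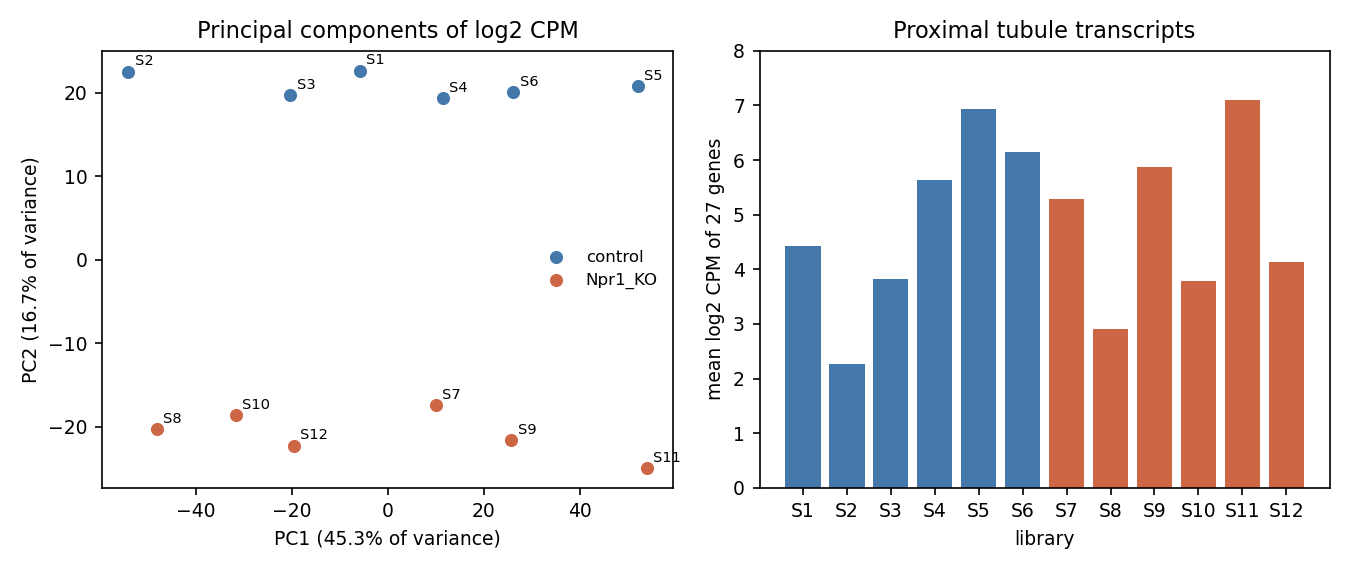
Left, the first and second principal components of log2 CPM over the tested genes, with 1 point per library. Right, the mean log2 CPM of 27 proximal tubule genes in each library (bars). Both groups spread along the first component (45.3% of variance) and separate on the second (16.7%), and the tubule mean spans 2.27 to 7.09.

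In a principal component analysis, genotype separated the libraries on the second component (16.7% of variance, two-sided exact permutation p = 0.00217, the smallest possible here), not on the first (45.3%, p = 0.894). Control S2 and Npr1_KO S8, with the fewest proximal tubule transcripts, lay at one end of the first component, and control S5 and Npr1_KO S11, with the most, at the other. Control S1 and Npr1_KO S7 stood apart from the other 10 libraries on the third component (8.02% of variance), 1 of each group, and the cause was not tested.

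Over the 30 lists tested, 6 passed with camera at its preset correlation of 0.01 and 0 with an estimated correlation. With fry, which asks whether a list's own genes move on balance, 5 passed (the cGMP, complement, mesangial, interferon and parietal lists), and 20 passed when changes in either direction count. The median, mean and test differed in sign for the coagulation, renin-angiotensin, growth factor, cell cycle, cGMP and endothelial lists. In 81 of 99 other splits of the 12 libraries into groups of 6, as many lists or more passed the preset camera test, whereas no other split drawn gave more than 2 changed genes. Among the genes named by rule, calls also ended with library size as covariate for Akap12, Casp8, Cox6c, Ctsz, Elovl6, Gbp2, Ifit3, Laptm4a, Mdm2, Nr4a1, Nr4a3, Rtp4 and Wipi2, with the mesangial covariate for Akap12, Bbc3, Casp8, Cox6c, Ctsz, Ifit3, Mdm2, Nr4a1 and Wipi2, and without control S5 and Npr1_KO S11 together for Akap12, Casp8, Cox6c, Ctsz, Elovl6, Laptm4a, Myl12a, Nid1, Tagln and Wipi2.

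**Figure D4:**
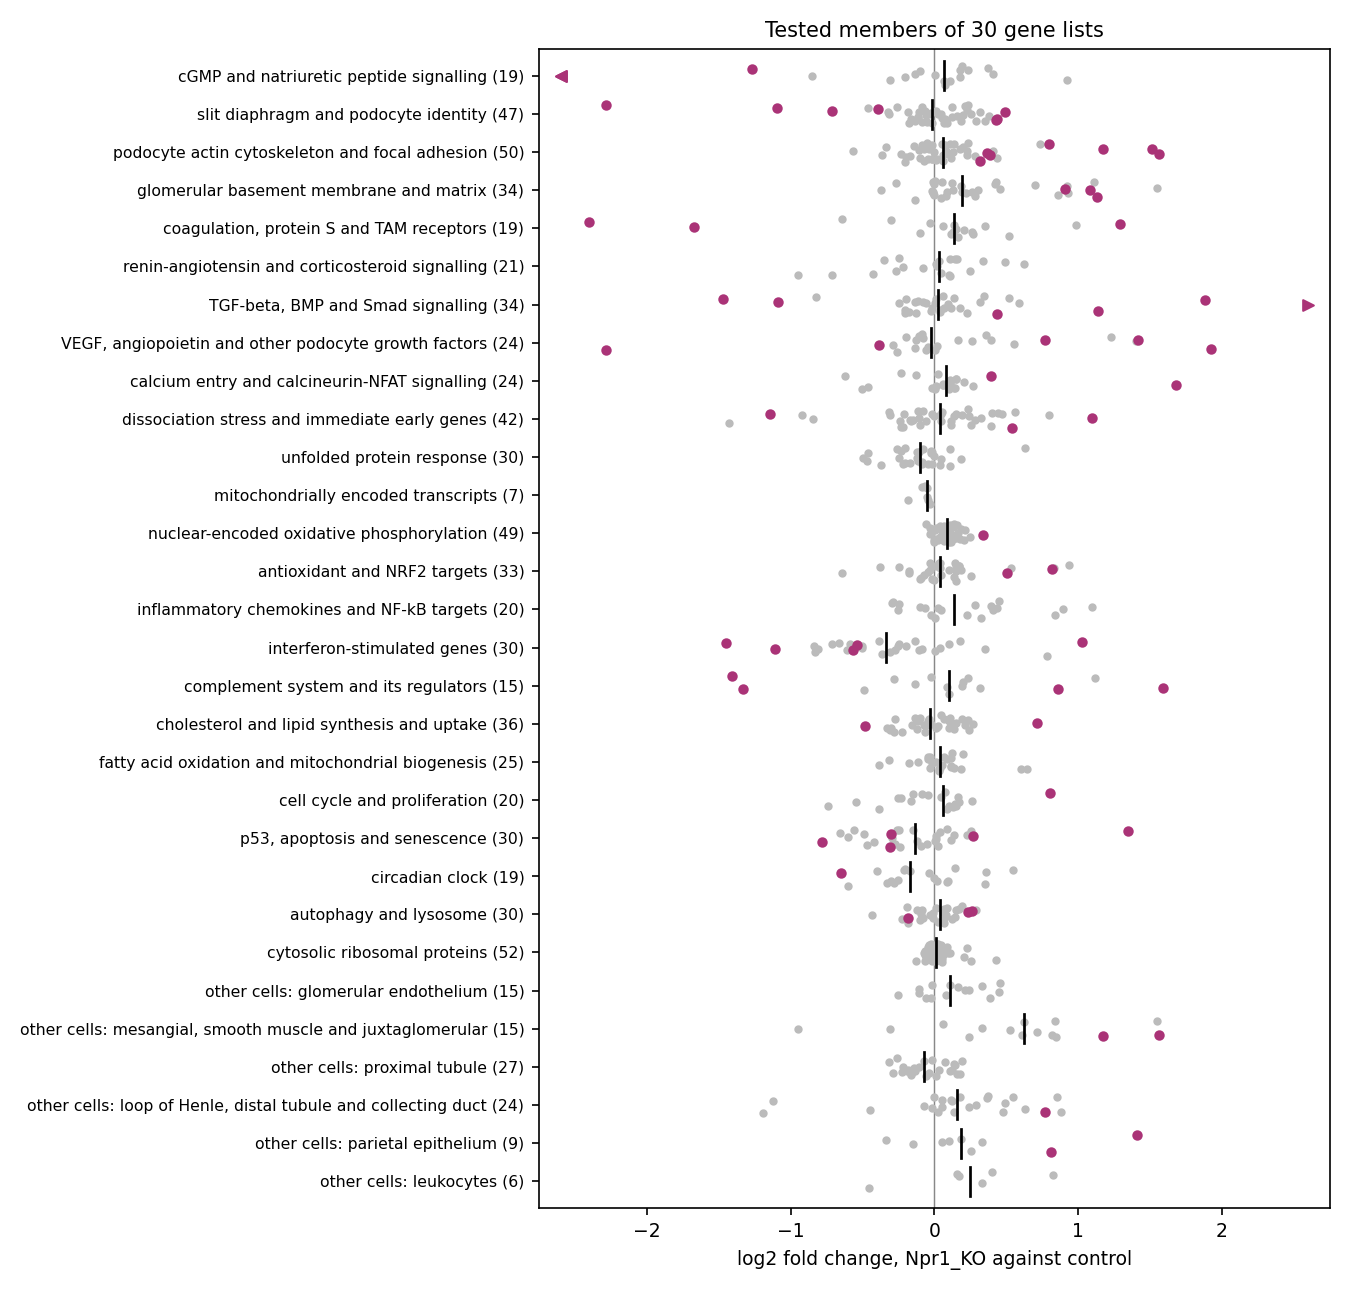
Log2 fold change, Npr1_KO against control, of each tested member of the 30 gene lists (number tested in parentheses), with changed genes in purple, other members in grey and the median of each list as a black line. Triangles at the edge mark Npr1 (-6.94) and Pde10a (-4.82) at the left and Ltbp2 at the right, beyond the limits of -2.6 and 2.6. The interferon list has its median at -0.34 and the mesangial list at 0.62.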

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

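All tests of explanations in this part were chosen after the result was seen, except the counts over other splits of the libraries. The number of changed genes, 691, was larger than chance gave, although single calls among them can still be false. Of 100 splits of the 12 libraries into groups of 6, drawn from 462, 1 gave as many, the real one, and the highest of the others gave 2. Every split but the real one mixed the genotypes, which can lower its count, so the splits speak for the total only. For the gene lists chance cannot be excluded. In 82 of 100 splits, the real one included, at least 6 lists passed the preset camera test, and the highest other split had 16. Taken list by list, the camera p was as small in 7 of 100 splits for the mesangial list, 13 for the interferon list, 15 for the matrix list, 23 for the actin list and 58 for oxidative phosphorylation. For the cGMP list such splits say little, since it holds the deleted gene Npr1, and it lost its call when chromosome 3 was left out.

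Changed genes were in excess on chromosome 3, and an effect of the altered Npr1 gene reaching up to 10 Mb stays possible, as the share 10 to 50 Mb away (8.49%) lay below the 95th percentile of windows of 40 Mb on other chromosomes (9.67%) and narrowly below that of paired stretches placed alike around other centres (8.98%, a comparison added last), although between 120 and 130 Mb 8 of 37 genes changed (21.6%). A narrower form was tested only after that result. An effect on neighbours less than 2 Mb away is unlikely to be the whole source, since 18.38% of genes 2 to 10 Mb away changed. That share lay above the 95th percentile of 457 windows of 20 Mb on other chromosomes (11.15%) and of paired stretches (12.12%). It was above the highest paired stretch (17.5%), though below the highest window (21.21%). A linked stretch of DNA carried with the floxed allele may contribute, and its reach beyond 10 Mb stays open because the share of 8.49% lay above the median (5.39%) of windows of 40 Mb. A response to receptor loss stays open too: of 81 ribosomal protein genes, Rps3a1 and Rpl34 changed, and both are among the 4 on chromosome 3 (Fisher's exact p = 0.00185), but 2 changed genes do not decide, and near Npr1 linkage and response cannot be told apart because the floxed allele and the deletion come together.

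For the higher actin and focal adhesion genes, mesangial or smooth muscle cells carried through the sort were not ruled out as a source. With the mean of 13 mesangial markers outside the actin list as covariate, 6 of the 7 genes stayed past the threshold. The median log2 fold change was 0.815 against 0.797 without it. Msn fell short at 0.318 (SE 0.092) against 0.319 (SE 0.08), through a wider error. These markers were rare, with a mean of 0.125 ± 0.324 log2 CPM in controls and 0.482 ± 0.461 in knockouts. A covariate of such spread may correct too little, so it cannot exclude carry-over. No difference in dissociation stress was detected. The mean of that list was 8.84 ± 0.191 log2 CPM in controls and 8.83 ± 0.32 in knockouts (two-sided exact permutation p = 0.922). With this mean as covariate 7 of 7 stayed past the threshold, but a covariate so alike in both groups can hardly move the fold changes and decides nothing. A difference in library size stays open for part of the pattern: with it as covariate 4 of 7 stayed and the median log2 fold change was 0.795, while Itgb1 went from 0.385 (SE 0.09) to 0.329 (SE 0.101), Tagln from 1.175 (SE 0.281) to 1.166 (SE 0.321) and Msn from 0.319 (SE 0.08) to 0.24 (SE 0.08). Tagln fell short mainly through a wider error, so only the smaller estimates of Itgb1 and Msn leave library size open. A response to the genotype is likewise open, and some carry-over may remain, since 11 of the 13 mesangial markers were higher with 0 changed.

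Proximal tubule transcripts varied between libraries. The genotype accounted for 0.007% of the variance of the list mean, and controls (2.27 to 6.93 log2 CPM) spanned almost the range of knockouts (2.92 to 7.09). RNA or cells of the tubule carried into the sort is a candidate source, since 1 component held 96.6% of the variance of the 24 members with at least 10 CPM. The listed genes made up 0.0475% to 0.918% of all counts, with Kap and Gpx3 the most abundant, in a sort that should remove tubule cells. No biological explanation other than genotype was tested.

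Of 284 sets of 6 libraries examined, 11 had 1 library far from the rest, fewer than the 1 in 20 that chance gives. Control S1 stood apart for the slit diaphragm list mean (8.857 log2 CPM, others 9.075 to 9.173), for Serping1 (3.326 log2 CPM, others 4.061 to 4.313) and for the share of counts from Podxl (0.9249%, others 1.187% to 1.328%). Control S4 was low for Nfkbia (10.18 log2 CPM, with the highest of the others at 10.61), and control S5 was high for the renin-angiotensin list mean (5.197, others 4.134 to 4.423). Npr1_KO S7 was high for Spry1 (2.079 log2 CPM, others 1.491 to 1.707) and low for Rcan2 (4.768, others 5.607 to 6.05). Npr1_KO S8 was high for 6330410L21Rik (3.222 log2 CPM, others 2.748 to 2.89) and for the actin list mean (7.722, others 7.435 to 7.525). Npr1_KO S10 was low for the complement list mean (2.557, others 2.795 to 2.932), and Npr1_KO S11 was high for the fatty acid oxidation list mean (5.645, others 4.873 to 5.085).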

How the results depend on the processing

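The alternatives without control S5 and Npr1_KO S11, with both tubule lists or mesangial markers as covariates, and without chromosome 3 were chosen after seeing the data. No named gene or list past the threshold changed direction under the alternatives that gave it a value, while genes that did not pass, such as Gpx3 and Kap, took either sign. Npr1 and Pros1 stayed past the threshold in the 35 alternatives run for them, which do not include leaving out chromosome 3, with log2 fold changes of -7.08 to -6.83 and -2.52 to -2.23 when 1 library was left out. The number of changed genes ranged from 471 (without Npr1_KO S9) to 686 in those fits, of higher genes from 243 to 341, of lower genes from 228 (without Npr1_KO S9) to 355, and of lists from 5 to 8. DESeq2 called 1115 genes (585 higher, 530 lower), which included all 691. An adjusted p of 0.1 gave 1045 (536 higher), and a fold of at least 1.5 left 368 (182 higher, 186 lower), both by construction. Lower genes numbered 533 with 1 surrogate variable, 534 with the proximal tubule covariate and 545 with the stress covariate. The surrogate variable followed the proximal tubule mean (absolute Pearson r = 0.99). The stress list mean was 8.29 log2 CPM in Npr1_KO S11 and 9.04 in control S2, the libraries with the most and the fewest proximal tubule transcripts. These fits therefore adjusted for much the same difference between libraries, and the cause of the larger numbers was not tested further. Leaving out control S5 and Npr1_KO S11 gave 447 genes (223 higher, 224 lower), with fewer libraries, and the mesangial covariate gave 218 lower genes, for which the cause was not tested. With an estimated correlation 0 lists passed. For other named genes 3219 comparisons with an alternative kept their side of the threshold, 212 fell short of it and 16 newly passed it. Comparisons past the threshold in neither fit count as kept even where the sign changed. For lists these numbers were 1065, 22 and 19. Under the scalings tried, the median log2 fold change of all genes lay between -0.0136 and 0.0003. No paired analysis was possible because the columns of the tables carry no replicate numbers, so the replicate block was not run. The Xist covariate was not run because Xist did not vary. The Y-linked gene Ddx3y was present in every library, from 125 CPM in control S5 to 243 CPM in Npr1_KO S8. Every library thus reads as male, and females were not examined. Depth limits the fold changes of genes with few counts in controls, such as Gm16048 and Ltbp2.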

Other observations

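The genes and tests in this part were chosen after their values were seen. Phosphodiesterase genes were lower beyond the members named so far. Of 13 cyclic nucleotide phosphodiesterase genes tested, 6 fell and 0 rose. Besides Pde7b and Pde10a these were Pde4d (37.6 ± 5.02 to 18.6 ± 2.73 CPM), Pde8a (9.75 ± 2.18 to 3.32 ± 1.08), Pde4b (554 ± 70.8 to 390.0 ± 72.8) and Pde4c (28.3 ± 4.15 to 16.9 ± 4.71). A feedback of cGMP on the enzymes that break it down may be asked about. Of 6 members that hydrolyse cGMP, 1 fell, and of 7 specific for cAMP, 5 fell (two-sided Fisher's exact p = 0.103), so most lower members are specific for cAMP, and the number of genes is too small to separate the classes.

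Some single genes outside the lists, picked one by one, also changed. Wif1, a secreted Wnt inhibitor, fell from 333 ± 84.0 to 54.4 ± 17.1 CPM (log2 fold change -2.61, adjusted p = 4.39e-05). Rspo1, a secreted Wnt enhancer, rose from 11.8 ± 5.47 to 53.6 ± 24.3 CPM, and Nkd1, a Wnt target and inhibitor, from 10.8 ± 5.77 to 52.0 ± 8.995 CPM. Smyd1, a muscle histone methyltransferase gene, rose from 18.5 ± 5.85 to 114 ± 46.6 CPM, Myl7, an atrial myosin light chain gene, from 63.6 ± 30.1 to 184 ± 39.7 CPM, and Cacna1s, a skeletal muscle calcium channel gene, from 4.52 ± 2.12 to 19.5 ± 6.32 CPM. Abra, an actin-binding Rho activator gene, rose from 13.01 ± 7.08 to 51.5 ± 10.7 CPM. No gene group was tested with them.

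Of 15 tested members of a list of ERK targets and feedback genes, 5 fell, all among those that had prompted the list, and 0 rose. Spry1, which lies on chromosome 3, and Dusp6 were among the 5. Spry4 was too, but was rare, with 1.405 CPM in controls and 0.338 CPM in knockouts. The others, Spry4, Spred1 and Il17rd, had log2 fold changes of -2.04, -0.66 and -1.07, whereas Spry2, Spred2, Dusp4 and Dusp5 did not pass (-0.30, -0.35, 0.15 and -0.11). The receptors Fgfr1 and Fgfr2 fell from 420.2 ± 36.5 to 299.8 ± 22.6 and from 134 ± 20.3 to 101 ± 10.9 CPM. Lower ERK signalling in podocytes without the receptor is a hypothesis. It was tested on the 10 tested members of a textbook list of ERK targets that had not prompted the list, which had a median log2 fold change of -0.29, with 0 changed. Camera gave p = 0.00795 for them and 0.0433 with an estimated correlation, but 18 of 100 splits of the libraries gave as small a p. These splits were not matched for tubule transcripts, which limits that count. The count of splits was added as a criterion after the camera p was known, and it leaves chance open for this set.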
